A study of Drosophila melanogaster with 8 samples.

How the data were processed

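RNA immunoprecipitation sequencing was deposited for tagged SXL, SSX and GFP in SL2 cells, with 8 samples in the series and 7 IP libraries in the tables. Per the labels' protocols, RNA from anti-FLAG precipitates was depleted of ribosomal RNA, made into stranded libraries with a low-input kit and sequenced in paired ends. Per the submitters' processing notes, Trimmomatic, TopHat2, featureCounts, DESeq and DESeq2 and the genome build BDGP6 were used, with no versions or roles given in the sources used here; whether counting used the strand was also not given, so overlapping and antisense genes are uncertain.

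The authors deposited 3 full comparison tables of 17559 genes and 2 shorter lists. Per the file headers, the full tables hold the authors' mean normalized signal per gene, a log2 fold change, its standard error on the log2 scale, a test score, a p-value and an adjusted p-value. The mean normalized counts were identical in the 3 tables, so 1 fit of the 7 libraries is implied. The shorter lists, per the file headers, add the read counts of each library as the authors deposited them, with gene names, other annotation columns and BDGP6 coordinates. Each list holds exactly the genes with a deposited log2 fold change above 2 and an adjusted p under 0.001, 199 for SXL and 947 for SSX, with 190 in both and 956 in either. Each library's size factor was solved by least squares from the deposited counts and the authors' mean normalized count, and normalized counts per library are counts divided by it; 14 further per-library columns were not used.

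The design fixed before the data were examined foresaw edgeR on counts if these were given for all genes. Counts were at hand for the listed genes only, so the results are those of the authors' deposited tables at an adjusted p of 0.05, and edgeR 4.0.16 (quasi-likelihood, R 4.3.3) with the authors' size factors was run on the listed genes as an added check, with DESeq2 1.42.0 as an alternative. These genes had been selected on the outcome, so that check says how calls depend on libraries and not whether genes are enriched. On simulated counts for the 956 genes, edgeR recovered 65% (SXL against GFP), 71% (SSX against GFP) and 87% (SXL against SSX) of genes changed by a log2 of 1, and 96%, 99% and 100% of those changed by a log2 of 2. The simulation started every group, GFP included, at the mean normalized count over all 7 libraries. Listed genes had fewer GFP reads than that, so the rates against GFP are likely too high for these data. Other tests used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.

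Column numbers did not follow the sample titles for SXL and GFP, so libraries were used as members of their group, named here by column number. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicate pairs differed by more than sampling noise: the chi-square per degree of freedom over listed genes was 1.27 for the GFP pair (p = 2e-06), and with all libraries thinned to the smallest total it was 1.22 for GFP, 3.68 for SXL and 1.32 to 1.99 for SSX, so none was counted as a duplicate.

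Names were taken from the lists (956 genes) and from RefSeq synonyms (189 genes); 16414 IDs had no name here. Named genes followed a rule fixed before the data were examined: per GFP comparison the 12 highest and 6 lowest log2 fold changes, and for SXL against SSX the 10 highest and 6 lowest, with an adjusted p under 0.05 and a mean normalized count of at least 50; every detected member of the bait, known target, dosage compensation and ELAV lists; and up to 4 members of lowest adjusted p in other lists described. The planned shift test of 29 gene lists could not be run, since most unlisted genes had no name. It was replaced by a two-sided Fisher exact test of list membership with the tested genes as background and every annotated member taken as tested, over 26 lists with at least 5 annotated members and Benjamini-Hochberg adjustment. That background is strict for over-representation and not for the opposite, so no depletion is reported; a one-sided test was added after the two-sided values had been seen. Chromosome shares used the same strict background. U-run tests were not run, since no genome sequence was used here. For a gene with 0 GFP reads the fold was computed against a floor of 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% counting interval. Alternatives covered thresholds, filters, adjustment, test, scaling, single libraries and a replicate block.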

Results

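RNA that co-purified with 2 related RNA-binding proteins was sequenced from SL2 cells, a male Drosophila melanogaster cell line that does not make the female splicing regulator Sex-lethal (SXL). The cells expressed SXL, its paralogue Sister-of-Sex-lethal (SSX) or green fluorescent protein (GFP), each with a FLAG and HA tag, and the tagged protein was collected with an antibody against FLAG. The series held 2 SXL IP libraries, 3 SSX IP libraries, 2 GFP IP libraries and 1 input control, which was not analysed here. The comparisons ask which RNAs were recovered with each protein above the GFP background and where the proteins differed. Read counts per library were at hand for 956 genes that the authors listed as enriched. Over these genes the SXL libraries held 3266209 and 3604413 reads, the SSX libraries 3383720, 4173927 and 4429899, and the GFP libraries 20859 and 27467. The size factors implied by the counts and the authors' mean normalized counts were 3.33 and 3.59 for SXL, 2.15, 1.94 and 1.87 for SSX, and 0.0886 and 0.120 for GFP. The median listed gene had 22 GFP reads over both libraries, 45 listed genes had 0, and 77 had 1 to 3, so the GFP side limited the precision of the fold changes against GFP.

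The transcript of the bait itself was the most enriched RNA with SXL. Normalized counts of Sxl (FBgn0264270, X, 7074550 to 7098056) were 33893 ± 929 (SD, n = 2) in the SXL IP, 4870 ± 1555 (SD, n = 3) in the SSX IP and 468 ± 7.44 (SD, n = 2) in the GFP IP. Normalized counts of ssx (FBgn0024987, X, 1370580 to 1375257) were 20862 ± 6285 (SD, n = 3) in the SSX IP, 507 ± 50 (SD, n = 2) in the SXL IP and 345 ± 54.1 (SD, n = 2) in the GFP IP. In the authors' deposited table Sxl had a log2 fold change of 6.06 with SXL (adjusted p = 5.6e-72) and 3.31 with SSX (adjusted p = 2.8e-25). In the authors' deposited table ssx had a log2 fold change of 5.84 with SSX (adjusted p = 7.6e-73) and 0.53 with SXL (adjusted p = 0.239). The bait transcripts can carry reads of the expressed construct, and the counting cannot separate these from reads of the cell's own gene.

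Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and the ATP synthase, filled most of the other top places with SXL. In the authors' deposited table all 12 named mitochondrial mRNAs rose with both proteins, and all 12 calls held when adjusted over the list alone. All 12 are in both of the authors' lists of enriched genes, so these directions and calls are not independent evidence. The transcript mt:ND4, a subunit of respiratory complex I, had log2 fold changes of 5.01 with SXL (SE 0.32) and 5.29 with SSX (SE 0.31) in the authors' deposited table. The transcript mt:CoIII, a subunit of cytochrome c oxidase, had 3.03 (SE 0.30) and 3.56 (SE 0.27) in the authors' deposited table. Normalized counts of mt:ND4 (mitochondrial genome, 8206 to 9544) were 8099.7 ± 1498 (SD, n = 2) with SXL, 9870.4 ± 2058 (SD, n = 3) with SSX and 235 ± 3.20 (SD, n = 2) with GFP. Among the 12, mt:CoI differed between the proteins, with a log2 SXL over SSX of -1.41 in the authors' deposited table (adjusted p = 6.2e-06). Against a background in which all 37 annotated mitochondrial genes were taken as tested, mitochondrial transcripts were over-represented in the SXL list (adjusted p = 3.9e-09, two-sided Fisher exact test) and in the SSX list (adjusted p = 0.0011).

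Other leading RNAs of the SXL IP were 2 short noncoding transcripts. CR43264 (X, 5831898 to 5832215) had a log2 fold change of 4.04 with SXL and 2.36 with SSX, and it was higher with SXL than with SSX by 1.68 (adjusted p = 2.1e-18) in the authors' deposited table. The small nuclear RNA snRNA:LU (2L, 3046746 to 3046904) had 4.07 with SXL (adjusted p = 0.00037) in the authors' deposited table and -0.49 with SSX (adjusted p = 0.682). Its normalized counts were 89891 and 10432 in the SXL libraries and 2295, 641 and 411 in the SSX libraries. The edgeR log2 fold change of snRNA:LU against GFP was 5.02 with both SXL libraries and 2.75 without SXL library 2. DESeq2 on the listed genes also gave 5.02 with both SXL libraries, so the lower deposited value is not a difference between these programs. No source used here says whether the deposited log2 fold changes were moderated towards 0.

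Across all genes, the authors' deposited table for SXL against GFP tested 7170 genes and 2110 passed an adjusted p of 0.05, of which 1175 were higher with SXL and 935 lower. The authors' deposited table for SSX against GFP tested 9034 genes and 4105 passed, of which 2364 were higher with SSX and 1741 lower. The median log2 fold change of the tested genes was 0.09 for SXL and 0.44 for SSX in the authors' deposited tables. With the values of the authors' deposited tables centred on these medians, the share of calls that were higher moved from 55.7% to 50.6% for SXL and from 57.6% to 42.5% for SSX. At a mean normalized count of at least 100 these shares of the authors' deposited tables were 70.0% and 73.9%, and at an absolute log2 fold change of at least 2 they were 46.2% and 62.3%. The most depleted genes carried no name in the tables used here; in the authors' deposited tables FBgn0036714 was the lowest with both proteins (-8.15 with SXL, -8.54 with SSX), and FBgn0031549 was next with SSX (-7.84; -7.48 with SXL).

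The highest fold changes with SSX, after its own transcript, belonged largely to genes with almost no GFP reads. CG12869, CG10801 and Zip89B had 0 GFP reads in both libraries, and their mean normalized counts with SSX, 251 ± 60, 240 ± 43 and 127 ± 23 (SD, n = 3), were at least 17.5-fold, 16.7-fold and 8.85-fold higher than the floor of 3 reads over the GFP group. The X-linked gene ogre, which encodes an innexin gap junction protein, also had 0 GFP reads and was at least 13.0-fold higher with SSX. CR44179 and Vmat, a vesicular monoamine transporter, had 1 GFP read each, and their ratios of SSX to GFP were 77.7 (95% counting interval 13.9 to 3068) and 72.2 (95% counting interval 13.0 to 2852). CG15211 and CR33963 had 7 and 9 GFP reads, with log2 fold changes of 4.90 and 4.92 in the authors' deposited table. These intervals and floors cover counting error only.

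**Figure D1:**
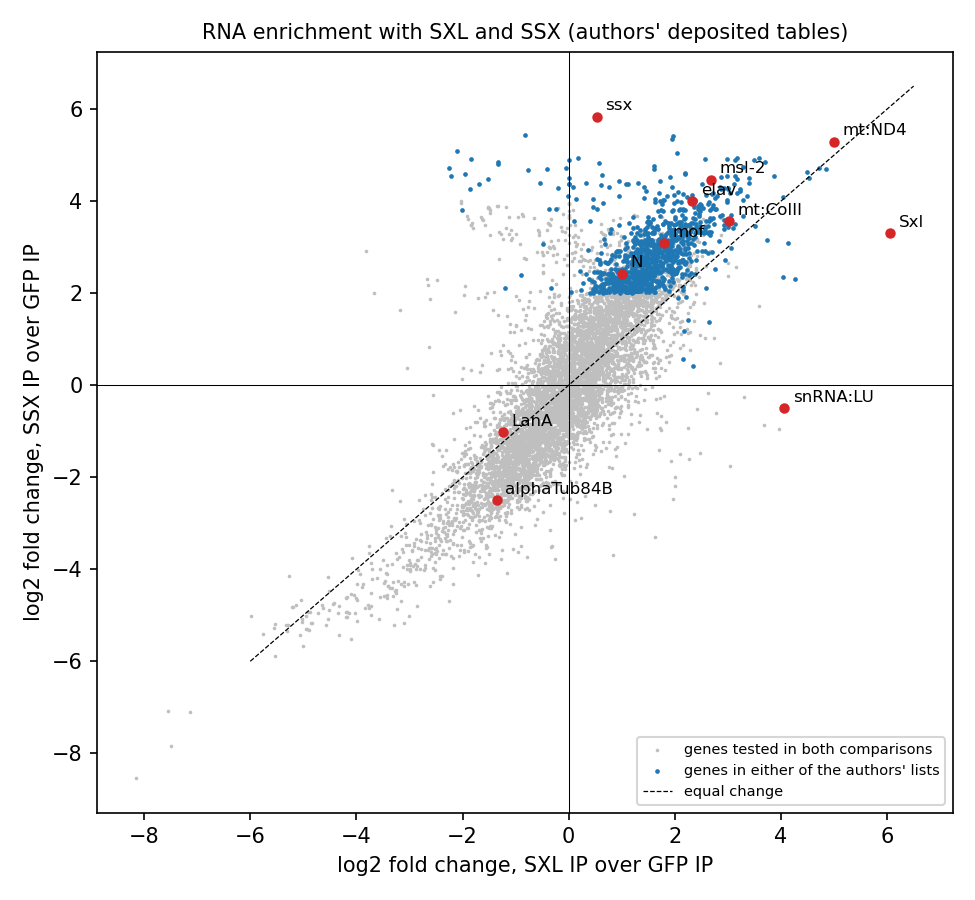
Log2 fold change with SSX over GFP (y axis) against that with SXL over GFP (x axis) for the genes tested in both comparisons of the authors' deposited tables; blue points are genes in either of the authors' lists, red points are named genes, and the dashed line marks equal change. Sxl (6.06, 3.31) and snRNA:LU (4.07, -0.49) lie below the line, and ssx (0.53, 5.84) and msl-2 (2.69, 4.47) lie above it.

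The mRNA of msl-2, whose translation SXL represses in females and whose product is a limiting subunit of the male dosage compensation complex, rose with both proteins. Normalized counts of msl-2 (2L, 3462218 to 3466112) were 893 ± 98.0 (SD, n = 2) with SXL, 3087 ± 696 (SD, n = 3) with SSX and 131 ± 21.6 (SD, n = 2) with GFP. The log2 fold change of msl-2 was 2.69 with SXL (adjusted p = 8.7e-12) and 4.47 with SSX (adjusted p = 4e-35), and SXL over SSX was -1.78 (adjusted p = 3.4e-12) in the authors' deposited table. The 956 listed genes had a median log2 SXL over SSX of -1.23, so a difference in this direction is common among listed genes. Since 947 of them had been selected for enrichment with SSX, that median is no neutral baseline for msl-2. Over all tested genes the median was -0.23 in the authors' deposited table. With edgeR scaled over the listed genes alone the msl-2 value was -0.52 (TMM) and -0.76 (equal totals). That scaling centres the selected genes, so it cannot test this direction. Of the known SXL targets, N, which encodes the Notch receptor, rose by 1.00 with SXL and 2.43 with SSX in the authors' deposited table. Phf7, a chromatin reader of male germ cells, rose by 2.85 with SSX in the authors' deposited table and had 1.30 with SXL (adjusted p = 0.174). Phf7 had 3 GFP reads, and its ratio of SSX to GFP was 9.09 (95% counting interval 3.11 to 44.1). Of the 4 named members of the known target list, Sxl included, 4 rose with SSX and 3 with SXL, with 4 and 3 adjusted over the list alone. All 4 are in the authors' SSX list, so their direction is not independent evidence. The list was over-represented among the genes listed for SSX (adjusted p = 0.0056, two-sided Fisher exact test) and not among those listed for SXL (adjusted p = 0.069). Without the bait Sxl the unadjusted p was 0.0098 for SSX (3 of 5 annotated members) and 0.131 for SXL. With Sxl, 4 members were listed for SSX where 0.63 were expected, and 2 for SXL where 0.17 were expected. The SXL list is shorter (199 against 947 genes), so its list tests have less power. A list that passed for SSX alone therefore does not show a preference of SSX over SXL.

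Some other dosage compensation genes also rose with both proteins, with 5 of 9 annotated members named here. The gene mof, a histone acetyltransferase, had log2 fold changes of 1.79 with SXL and 3.09 with SSX in the authors' deposited table. The gene msl-1 had 1.36 and 2.84, and msl-3 had 1.58 and 2.49 in the authors' deposited table. The noncoding RNA roX1 had 1.56 (adjusted p = 0.293) and 2.14 (adjusted p = 0.096) in the authors' deposited table, at a mean normalized count of 8.31. Of 5 named members 4 rose with each protein, and adjusted over the list alone 4 passed with SXL and 5 with SSX. The 4 that rose are in the authors' SSX list, so their direction is not independent evidence. Over-representation among the genes listed for SSX had an adjusted p of 0.021, and among those listed for SXL 0.65 (two-sided Fisher exact test). Listed members were 4 for SSX where 0.94 were expected and 1 for SXL where 0.25 were expected, so the SXL test had little power. The gene elav, a neuronal RNA-binding protein of the same family, had 2.33 with SXL and 4.01 with SSX in the authors' deposited table.

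Named SR and hnRNP splicing regulators and sex determination genes rose with both proteins. All 8 named SR and hnRNP genes rose with both, among them Hrb27C (1.88 with SXL, 3.47 with SSX), ps (1.44, 2.96) and sqd (2.08, 2.70), and 8 calls held adjusted over the list alone in each in the authors' deposited table. All 7 named sex determination genes rose with both, among them emc (2.39, 3.30), fru (1.37, 3.14) and fl(2)d (1.92, 2.49), a subunit of the m6A methyltransferase complex, and 7 calls held adjusted over the list alone in each in the authors' deposited table. Both lists were over-represented among the genes listed for SSX (adjusted p = 0.021 and 0.010, two-sided Fisher exact test) and not among those listed for SXL (adjusted p = 1 and 0.97). Only 0.80 and 0.56 members were expected among the genes listed for SXL, so the SXL tests had little power. Named members came almost wholly from the authors' lists of enriched genes, so the direction of these members is not independent evidence. Over-representation alone was tested. No list test accounted for gene length or expression, and listed genes were longer than annotated genes (median 7426 bp against 1710 bp).

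Listed genes also included members of signalling pathways and the cell cycle. The Notch pathway had 6 named genes that rose with SSX and 5 that rose with SXL in the authors' deposited table, with dx at 3.53 and neur at 3.16 for SSX. Over-representation of the Notch pathway among the genes listed for SSX had an adjusted p of 0.028 (two-sided Fisher exact test) and 0.052 in a one-sided test. The cell cycle list had 7 named genes that rose with SSX and 6 that rose with SXL in the authors' deposited table, among them stg, the Cdc25 phosphatase (2.09 with SXL, 3.24 with SSX), and CycE (1.93, 3.16). The cell cycle list had an adjusted p of 0.021 for SSX (two-sided Fisher exact test). The Hedgehog pathway had 4 named genes that rose with SSX and 3 that rose with SXL in the authors' deposited table, and that list did not pass (adjusted p = 0.074). None of the Notch, cell cycle and Hedgehog lists was over-represented among the genes listed for SXL (adjusted p = 1, 0.53 and 1). Only 0.56, 0.67 and 0.36 members of these lists were expected among the genes listed for SXL, so those tests had little power. Adjusted over the list alone, 6, 7 and 4 of these Notch, cell cycle and Hedgehog genes passed with SSX and 5, 7 and 3 with SXL. All of them are in the authors' SSX list, so their direction is not independent evidence.

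**Figure D2:**
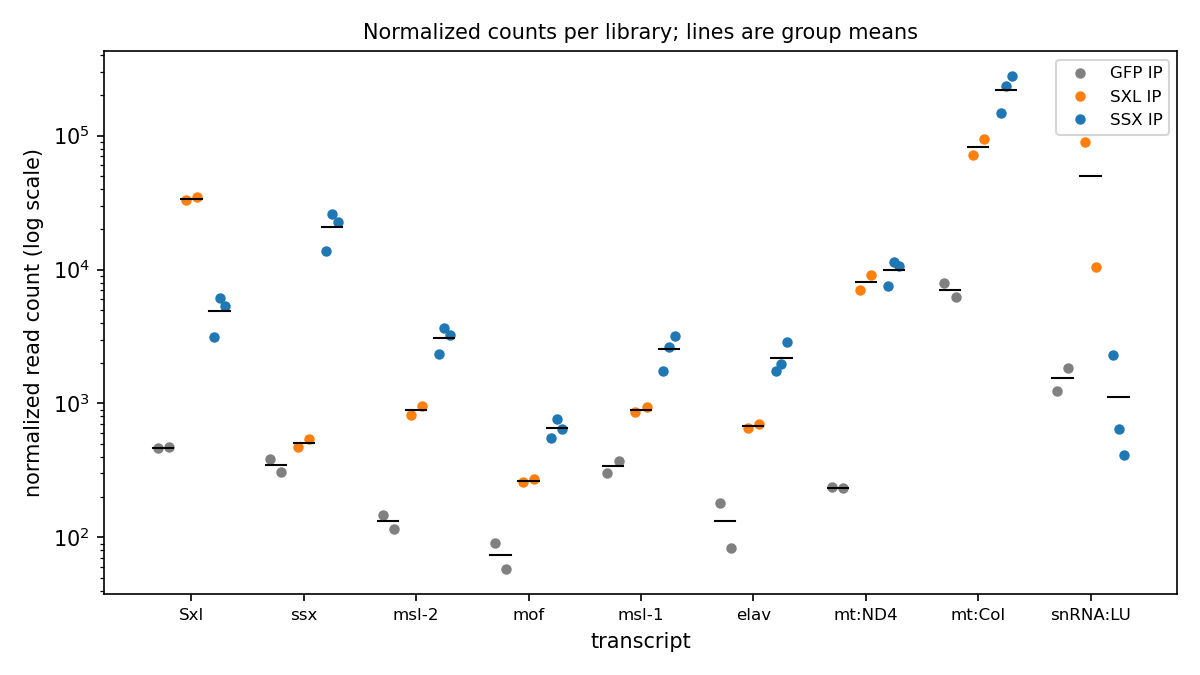
Normalized read counts per library (log y axis) of 9 transcripts in the GFP, SXL and SSX IPs; each point is 1 library and each line a group mean. The msl-2 means are 131 (GFP), 893 (SXL) and 3087 (SSX), and the SXL libraries differ for snRNA:LU (89891 and 10432).

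The direct comparison of the proteins on listed genes is shaped by how those genes were chosen, since 947 of the 956 had been selected for enrichment with SSX. Of the 956 listed genes, 865 were higher with SSX and 9 higher with SXL in the authors' deposited table, with a median log2 SXL over SSX of -1.23. Of the 199 genes in the SXL list, of which 190 were also in the SSX list, 148 were higher with SSX and 9 higher with SXL (median -0.97) in the authors' deposited table. Scaling over the listed genes alone moves all of them towards a common centre, so it cannot test this direction: with TMM, edgeR called 185 higher with SXL and 182 higher with SSX (median 0.02), and with equal totals of the listed genes 78 and 297 (median -0.21). Across all 9500 genes tested in the authors' deposited table, 1094 were higher with SXL and 2462 higher with SSX. With the values of the authors' deposited table centred on their median of -0.23, the share higher with SXL moved from 30.8% to 46.8%. Among genes with a mean normalized count of at least 50, the lowest SXL over SSX values in the authors' deposited table belonged to CR44179 (-6.27), CG17387 (-5.43), ssx (-5.30), Zip89B (-4.77), CG13243 (-4.26) and CR45140 (-4.20). The gene osk, a germ plasm organiser, had -3.15 (adjusted p = 2.1e-39) in the authors' deposited table. Of the 10 such genes highest with SXL over SSX, 9 had no name here. FBgn0086027 (4.92, SE 0.77) and FBgn0003935 (4.79, SE 1.03) led in the authors' deposited table. Neither had counts per library here, so their dependence on single libraries is unknown.

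The gene sets enriched with the 2 proteins overlapped. Among 7170 genes tested in both comparisons of the authors' deposited tables, 1099 were higher with both, where independent lists of 1175 and 2281 genes would share 374. Of these genes of the authors' deposited tables, 853 were lower with both, where independent lists would share 220. Simulated groups without effects that share the GFP libraries had 0.02 shared higher genes on average (100 simulations); that value leaves out the effects, and the count for independent lists leaves out the shared controls. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited tables had a Pearson r of 0.809 and a Spearman rho of 0.808, and shared controls alone gave a simulated r of 0.791. The covariance was 1.96 against a simulated 0.300. The GFP libraries could not be split with 2 per part, so part of the excess may come from the shared controls.

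X-linked genes made up 319 of the 947 genes listed for SSX (33.7%, exact 95% interval 30.7 to 36.8) and 72 of the 199 listed for SXL (36.2%, exact 95% interval 29.5 to 43.3), against 15.3% of all annotated genes. The chromosome of the tested genes that were not listed was unknown here. If every annotated X-linked gene had been tested, the share among tested genes was at most 30.2% for SSX (p = 0.0135, two-sided Fisher exact test) and 38.02% for SXL (p = 0.605). That bound is higher for SXL because fewer genes were tested (7170 against 9034), so these p-values do not show a difference between the proteins. In the authors' deposited table, listed X-linked genes had a mean log2 fold change with SSX of 3.05 and listed autosomal genes 2.86 (permutation p = 0.00026, two-sided). With SXL these means were 2.55 and 2.47 (permutation p = 0.330, two-sided). The permutation took genes as units, so its p-values do not measure the spread between libraries. All these genes had passed the thresholds of the lists, and gene length was not accounted for.

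**Figure D3:**
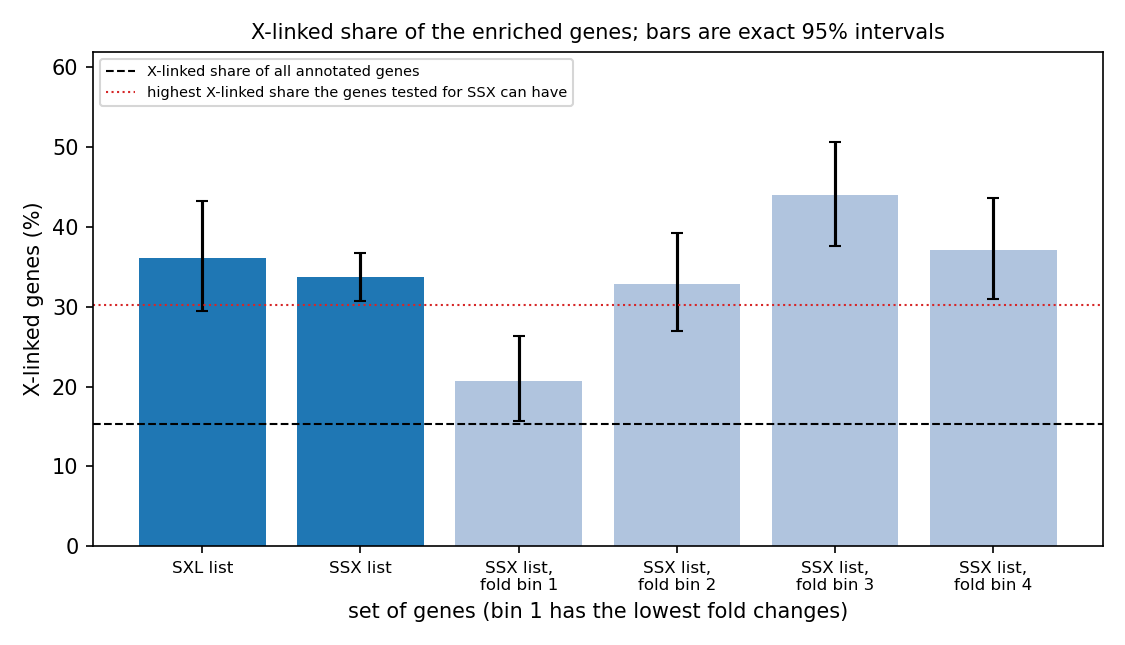
Percent of X-linked genes (y axis) in the SXL list, the SSX list and 4 equal bins of the SSX list by fold change, with exact 95% intervals; the dashed line is the share of all annotated genes (15.3%) and the dotted line the highest share the genes tested for SSX can have (30.2%). The share is 20.7% in the bin of lowest fold changes, 44.1% in bin 3 and 37.1% in the bin of highest fold changes.

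Few cell type markers had a name here, and those that rose with SSX were named because they are in the authors' lists, so their direction is not independent evidence. The hemocyte gene srp rose with both proteins (0.92, 2.46) and LanA fell with both (-1.23, -1.03) in the authors' deposited table. The neuronal gene futsch had 0.05 with SXL (adjusted p = 0.962) and rose by 2.03 with SSX, and the muscle gene Tm1 rose by 1.34 and 2.19 in the authors' deposited table. The germline gene osk had 3 GFP reads and a ratio of SSX to GFP of 37.1 (95% counting interval 12.7 to 180). The housekeeping gene alphaTub84B fell with both proteins (-1.36, -2.49) in the authors' deposited table.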

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

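The tests of reads shared between paralogues, of carry-over, of the tested genes' makeup, of GFP read number and of the mitochondrial genes were chosen after the results were seen; the test of gene length was chosen before.

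Effects against GFP differed between the proteins for 5 genes called in opposite directions with SXL and with SSX, each also different in the direct comparison of the authors' deposited tables; none has a name here. In the authors' deposited table snRNA:LU differed by a log2 SXL over SSX of 4.56 (adjusted p = 1.2e-05). On the listed genes this was 5.49 with edgeR and 5.49 with DESeq2. With edgeR it was 3.22 without SXL library 2. For the bait transcript ssx the log2 SXL over SSX was -5.30 in the authors' deposited table.

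Sxl reads in the SSX IP stood at 14.4% ± 4.6 (SD, n = 3) of the SXL IP level. Reads shared between Sxl and ssx are argued against as the whole cause: the ssx excess over GFP in the SXL libraries was at most 0.578% of the Sxl excess, while the Sxl excess in the SSX libraries was 19.6 to 22.0% of the ssx excess. Carry-over from the SXL libraries cannot be told apart from binding: 2 of the 3 SSX libraries had snRNA:LU below the level that such a share of the lower SXL library would give, and 1 did not. Binding of SSX to Sxl RNA stays open and was not tested otherwise.

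X-linked genes were frequent in the SSX list. A high X-linked share of the tested genes does not account for it, since the lower bound of the listed share was 30.7% against a highest possible 30.2%, a narrow margin. Listed genes were longer than annotated genes (median 7426 bp against 1710 bp). Against all annotated genes, length alone does not account for the share. The odds ratio for X was 3.10 unstratified and 2.78 (95% interval 2.39 to 3.23) over length deciles of the annotation. That background includes genes not tested, so expression of X-linked genes in these cells stays open. With every annotated X-linked gene taken as tested, the odds ratio among tested genes was 1.20. No length strata were formed there, so length among tested genes stays open too. The SXL list had a similar X-linked share (36.2%), and 190 of its 199 genes were also in the SSX list. Against all annotated genes the odds ratio was 3.21 for SXL and 3.06 for SSX, so the share is not particular to SSX. A preference of both proteins for X-linked RNAs may be one hypothesis and was not tested.

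All 12 named mitochondrial mRNAs were higher in both IPs, which follows from their place in both of the authors' lists. The 4 transcripts with at least 100 GFP reads had a lowest 95% bound of the log2 fold change of 2.45, so their rise does not rest on few GFP reads. They had been listed for a log2 above 2 and an adjusted p under 0.001, so a high bound was nearly fixed in advance. For the other transcripts, which had fewer GFP reads, the test cannot decide. An equal gain of all mitochondrial RNA is argued against by heterogeneity between the 12 transcripts beyond their standard errors (chi-square, larger p = 2.57e-06). A difference between the strands goes with the values: the 4 minus-strand genes averaged 4.76 ± 0.22 with SXL and 4.84 ± 0.31 with SSX (SD over genes) against 3.74 ± 0.52 and 3.91 ± 0.70 for the 8 plus-strand genes (larger p = 0.0364, exact two-sided permutation test; adjusted p = 0.016 and 0.036). Both comparisons use the same GFP libraries, so their agreement is not independent, and a strand difference in the GFP libraries alone would show in both. The test takes each gene as a separate unit, but the minus-strand genes mt:ND5, mt:ND4 and mt:ND4L lie side by side (6402 to 9834). GFP reads ran from 32 to 96 for the minus-strand genes and from 7 to 2368 for the plus-strand genes, and read number was not accounted for. The test used the deposited log2 fold changes, which may be moderated towards 0. The strand difference may also reflect sequence content, which was not tested.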

How the results depend on the processing

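Alternatives chosen after seeing the data were the mean count of at least 200, centring, equal totals of the listed genes, the annotation backgrounds, the fold of at least 3 for X-linked genes and the one-sided list test. Calls for SXL against GFP, SSX against GFP and SXL against SSX (2110, 4105 and 3556) became 606, 2261 and 724 at an absolute log2 of at least 2, 661, 1702 and 1188 under Bonferroni, 1187, 1592 and 1318 at a mean count of at least 200, and 2204 and 1810 for the latter pair at a mean count of at least 100, all stricter by construction, Bonferroni over every gene with a p-value (12297); SXL against SSX fell to 2327 at an absolute log2 of at least 1. Centring gave 2118, 4181 and 3612 calls. The overlap became 258 at a log2 of at least 2, and the correlation 0.907 at a mean count of at least 100, where shared controls alone gave 0.739. With edgeR on the listed genes, 199 SXL-listed, 947 SSX-listed and 898 of 956 genes for SXL against SSX passed; with TMM over the listed genes these became 83, 147 (98 higher, 49 lower) and 367 (185 higher with SXL, 182 with SSX), and with equal totals of the listed genes 30, 213 (65 higher, 148 lower) and 375 (78 higher with SXL, 297 with SSX). Both scalings set the centre of genes that had all been selected as higher towards 0, which removes shared enrichment by construction; the same scalings brought Sxl with SSX to 0.54 and 0.22 (log2; adjusted p = 0.143 and 0.477, no longer called) and msl-2 with SXL to 1.22 and 0.68 (adjusted p = 0.0066 and 0.065, the second no longer called), and made falls of snRNA:LU with SSX (-3.13 and -3.39) and of ssx with SXL (-0.99 and -1.53, adjusted p = 0.017 and 0.00023; 0.56 and not called in the main fit) pass. The lost calls therefore do not count against enrichment. Without counts of unlisted genes, the only alternative to the authors' scaling over all genes was centring. Centring moves all genes alike, so it shows how the calls depend on the centre and not whether that scaling is right. Without SSX library 1, ssx with SXL was called as higher (0.57, adjusted p = 0.038). Leaving out 1 library gave 199 to 199, 945 to 947 and 762 to 917 calls; the GFP calls could hardly change, since the genes had passed stricter thresholds, and log2 fold changes of at least 2 held for 174 to 199 of 199 and 882 to 947 of 947 genes; where this leaves 1 library in a group, it is assumed to vary like the others. The column number as a replicate block gave 199, 947 and 922 calls; the numbers do not pair the libraries (correlations 0.12, -0.03 and 0.06), and the block changed no call of a named gene tested, except that snRNA:LU with SSX passed at -1.74, as it did without SSX library 1 (-1.56). The X-linked share of the SXL list, 36.2%, went from an odds ratio of 0.922 to 3.21 with all annotated genes as background; the bound on tested genes is too wide to decide between them. Gene lists over-represented numbered 1 for SXL and 7 for SSX, 2 and 8 with all annotated genes, and 1 and 6 one-sided. Not run were the U-run and list-shift alternatives; the planned stricter p and fold for X-linked genes are already met by the lists. With only the lists cut at a mean count of at least 100, the X-linked share was 36.4% for SXL and 34.6% for SSX. The background of tested genes was not cut. The p-values (0.656 and 0.0041, two-sided Fisher exact test) therefore compare unlike sets and are no check on the main values. Depth in the GFP IP, with 281 listed genes under 10 reads, limits the fold changes against GFP.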

Other observations

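Heat shock and chaperone genes had 3 named members, and all 3 rose with both proteins in the authors' deposited table: DnaJ-1 by 2.40 and 2.72, Hsc70-3, the chaperone of the endoplasmic reticulum, by 1.35 and 3.37, and Hsp60 by 0.71 and 2.04 (SXL, SSX). These 3 are in the authors' SSX list, as are Thor, Unr, His3.3B and mRpS5 below, so their direction is not independent evidence. The chaperone list was not over-represented for SSX (3 of 21 annotated members where 2.20 were expected, adjusted p = 0.654, two-sided Fisher exact test) or for SXL (adjusted p = 0.97). In the authors' deposited table the translation inhibitor Thor rose by 1.64 and 2.51, Unr, a partner of SXL on msl-2 mRNA, by 1.63 and 2.02, and the replacement histone gene His3.3B by 1.51 and 2.88. The gene mRpS5, a mitochondrial ribosomal protein gene, rose by 2.20 with SSX, and the splicing factor gene Prp31 had -1.10 (adjusted p = 0.156) and -0.78 (adjusted p = 0.266) in the authors' deposited table. Cytosolic ribosomal protein, snoRNA, ribosomal RNA, antimicrobial and follicle cell lists had 0 named members with reads. Matched by name, 0 of their members were therefore in either of the authors' lists. How many of these members were tested is unknown here, so depletion cannot be judged. The transposable element list matched 0 annotated genes, so nothing can be said of it here. Chromosome 4, the small autosome, held 19 of the 947 genes listed for SSX (adjusted p = 0.096, one-sided Fisher exact test).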
